A study of Drosophila melanogaster with 4 samples.

How the data were processed

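All libraries of ovarian RNA, 2 of a control and 2 of a tumor genotype, were used, and group and replicate number were taken from the sample titles. Per the labels' protocols, RNA was isolated with a column kit and libraries followed standard Illumina steps, and per the series description they were sequenced on a HiSeq4000. Per the submitters' processing notes, reads were quantified with kallisto, whose version, genome build, annotation and strand setting are not given in the sources used here. Per the file headers, the authors deposited for each gene the target length, the effective length, the estimated count and the TPM. Estimated counts are reads that kallisto shares out among targets and need not be whole numbers, and the deposited TPM values divide them by effective length and scale each library to the same total. Each file lists 17773 gene identifiers, 17668 of which matched a symbol in the name table used here, and 12955 had a value above 0 in at least 1 library. Values of 1000000 or more, of which there were 3, keep 3 significant digits in the files. No sample column of the files went unused.

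The deposited lengths were compared with the Ensembl release 115 annotation of BDGP6.54, from which all coordinates come. For 17551 of the 17668 annotated genes (99.3%) the target length equals the annotated span, introns included, plus 4000 bases, which corresponds to 2000 bases on each side. Such targets overlap. For 90.2% of the genes the target holds an exon of another listed gene, and 11815 genes have no exon sequence of their own outside other targets. Reads from overlapping genes, from introns and from transposable elements inside a span can therefore enter a gene's count, and kallisto's division of them between targets can differ between libraries. To gauge this, locus sums were made by adding the counts of every target that holds an exon of the gene, and each was tested in place of the gene's own count. Genes were called resolved where at least 50% of their exon sequence lies outside other targets, every protein-coding gene with exons in the target meets the same limit, and the other genes in the target have a lower summed mean count. Of 1322 resolved genes, 670 were tested. The share of each target covered by annotated transposable elements was computed from the same annotation. These measures were chosen after the data were examined.

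Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM factors, glmQLFit and glmQLFTest on group alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are tumor over control with the SE of the fit. With 2 residual degrees of freedom the test borrows its spread across genes. Totals of 41248098 to 50971937 counts per library set the counting error, which is small for most genes named, so that the spread between replicates limits precision. The floor used for near-0 genes was 3 counts in each library, and it covers counting error only. Gene lists and families, 44 in all, were fixed before the data were examined and tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 3 tested members. No list passed with an estimated correlation, where the smallest adjusted p was 0.43. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for joins and figures.

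The rule for named genes was also set in advance. It took (a) the targeted genes, the driver gene and 19 further genes chosen from the subject of the study, (b) the 12 highest and 12 lowest log2 fold changes among called genes with an average log2 CPM of at least 4 and both tumor libraries on the same side of both control libraries, and (c) up to 4 called members with the smallest adjusted p in each list. All genes of (a) and (b) are named, and those of (c) for the lists past the threshold and for lists on secreted factors, JAK-STAT, Notch, follicle identity, matrix and cell cycle. For other lists some genes of (c) are named. Genes outside the rule are said to have been chosen after their values were seen.

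The fitting steps were tested on simulated counts for this comparison, in which 200 of 9235 tested genes had known changes. The edgeR test recovered 36 of 50 genes at a log2 fold change of -3, 11 of 50 at -1, 19 of 50 at 1 and 49 of 50 at 3, with 1.71% false calls among all calls. In it the counts of each target were drawn apart, and few genes changed, equally in both directions. It therefore does not cover reads divided between targets or the choice of scaling. Alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors, library totals, TMM on ribosomal protein genes, scaling without germline, meiosis and eggshell lists, no filter and a stricter filter, DESeq2 1.42.0 and limma-voom, a replicate block, leaving out each library, limma-trend on log2(TPM + 1) with pseudocounts of 0.1 and 5 as well, other thresholds, and other set tests. Locus sums, the same with list members that share a sum counted once, resolved genes, and leaving out small RNA and mitochondrial genes or targets of which 20% or more is transposable element were added after the data were seen. The reads themselves were not analysed here.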

Results

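RNA was sequenced from ovaries of adult female Drosophila melanogaster of 2 genotypes after 20 days at 29 °C. In both, the tj-GAL4 driver, which is active in the somatic follicle cells of the ovary, was combined with a temperature-sensitive Gal80 repressor that is inactive at this temperature. The control genotype carried the driver and the repressor alone. The tumor genotype also carried UAS transgenes for a form of the atypical protein kinase C aPKC that lacks its N-terminal part and for the oncogenic Ras form RasV12. Each genotype had 2 libraries, which the series description calls biological replicates. Per the sample descriptions control tissue was restricted to follicles before yolk uptake, tumors were taken as they were, and both were dissociated with a bacterial protease and filtered to enrich follicle epithelial cells. The libraries held 41248098 and 50971937 estimated counts in control 1 and control 2, and 47512735 and 42739528 in tumor 1 and tumor 2. Across genes, log2(CPM + 1) correlated at r = 0.982 between the control libraries, 0.981 between the tumor libraries and 0.829 to 0.851 between genotypes, where genes are not independent replicates. The estimated counts of replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 93.8 in control and 138 in tumor. A division of reads between overlapping targets that differs between libraries can add to this value. It therefore does not by itself tell separate samples from 1 library read again or from separate preparations of the same RNA. The leading principal component held 89.2% of the variance and separated the genotypes. Targets of small nucleolar RNA genes took 12.89% and 12.72% of the counts in control and 8.92% and 8.64% in tumor, and the mitochondrial genome took 4.72% and 6.33% against 4.39% and 2.33%. The small nucleolar RNA genes have a median span of 134 bases, to which 4000 bases were added. Their targets are thus mostly flanking sequence, and their counts need not come from these RNAs.

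The comparison asks which genes differ between tumor and control tissue enriched for follicle epithelium, in a study whose title concerns clotting disorders and host death. Counts of both genes that the transgenes carry were higher in both tumor libraries. Estimated counts of aPKC (FBgn0261854, chromosome 2R, 14944458 to 14962969, minus strand) rose from 1910 and 2482 in control to 54944 and 73836 in tumor, a log2 fold change of 4.82 ± 0.23 (SE of the fit, n = 2 libraries per group, edgeR adjusted p = 0.0015). Ras85D (FBgn0003205, chromosome 3R, 9510561 to 9513067, minus strand) rose from 676 and 215 to 102550 and 109225, a log2 fold change of 7.75 ± 0.84 (edgeR adjusted p = 0.0051). The files give 1 value per gene, so transcripts of the transgenes and of the endogenous genes were counted together and the transgene forms were not seen apart. The driver gene tj (FBgn0000964, chromosome 2L, 19464267 to 19467758, plus strand), which encodes a Maf transcription factor of somatic ovary cells, had 15641 and 21837 counts in control and 13558 and 11159 in tumor, a fall of 0.66 ± 0.12 on the log2 scale (edgeR adjusted p = 0.016). The tj call ended when control 2 or tumor 2 was left out, with an adjusted p of up to 0.078, and under scaling to ribosomal protein genes its log2 fold change was -0.02.

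Of 9402 genes tested with edgeR's quasi-likelihood test, 2202 were higher and 1989 lower in tumor, so that 52.5% of the calls were higher. At a log2 fold change of at least 1 in size, 1488 were higher and 1141 lower. The genotype effect was large against the spread between replicates, whose biological coefficient of variation was 0.36. The counts of calls fell when any library was left out, and fell most without a control library. Without control 1 they were 1095 higher and 760 lower, and without control 2 they were 1229 and 946. The share of higher calls depended on the scaling, with 45.1% under upper-quartile factors, 59.6% under library totals, 66 to 66.8% on the TPM scale and 83.1% when libraries were scaled on ribosomal protein genes. It was 49.3% without tumor 1 and 50% without tumor 2. A limit applies to single genes: 99.3% of the annotated genes were quantified on a target that spans the gene with its introns and 2 kb on each side, and 90.2% of the targets hold an exon of another listed gene. Counts were therefore also added over every target that holds an exon of a gene, called the locus sum here. The locus sum changed in the same direction past the threshold for 1552 (70.5%) of the higher and 1367 (68.7%) of the lower genes, and in the opposite direction for 205 and 197. A locus sum holds the gene's own count, so a part of this agreement is built in. Among all 9402 genes, 2744 locus sums were higher and 2657 lower. Of 128 named genes called with counts in both groups, 63 had a locus sum that changed by a fold more than 1.5 times smaller than the gene itself or the other way, so the size of a single gene's change is uncertain where a locus is shared. Where no locus sum is given below, it need not match the gene's own change. For aPKC and Ras85D the locus sums rose by log2 fold changes of 3.32 and 3.09.

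**Figure D1:**
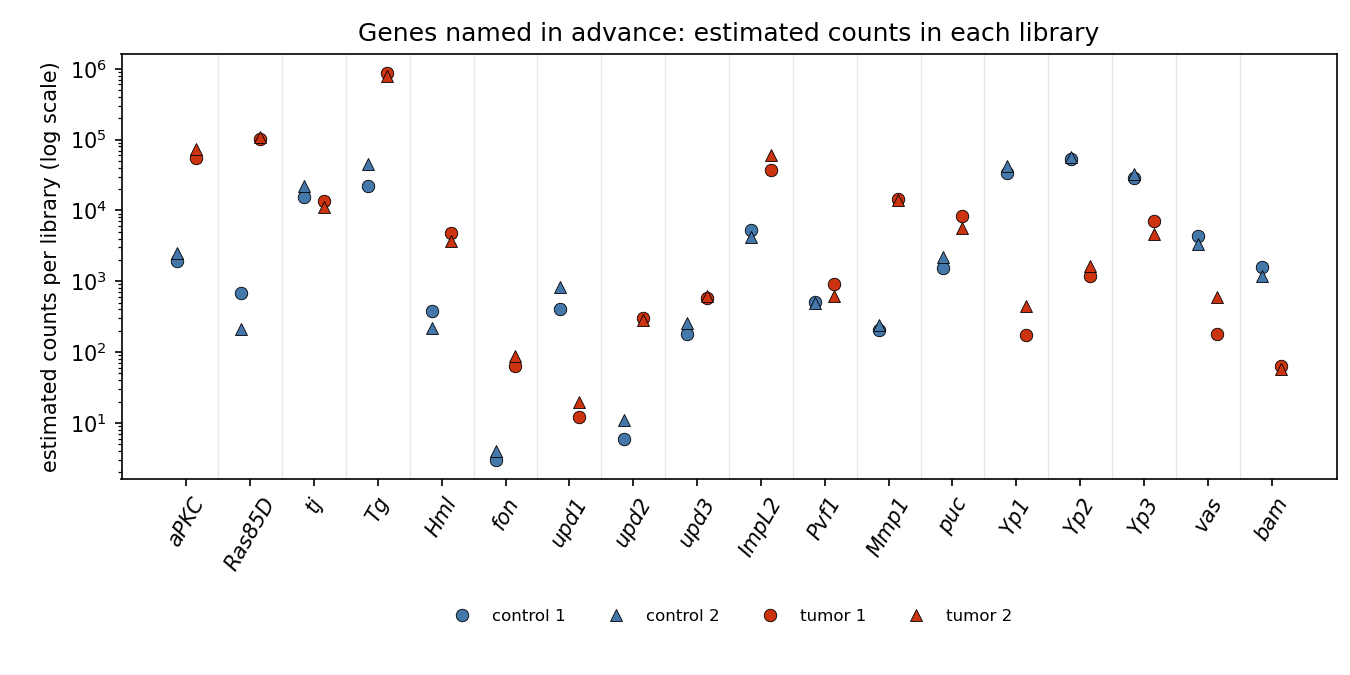
Estimated counts (log axis) of 18 genes named before the data were examined, with 1 point per library, control in blue, tumor in red, circles for replicate 1 and triangles for replicate 2. aPKC, Ras85D, Tg, Hml, upd2, ImpL2 and Mmp1 lie higher in both tumor libraries than in both control libraries, and upd1, the Yp genes, vas and bam lie lower.

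Genes for clotting and hemolymph proteins rose as a group. Of 20 tested members 10 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.0067, adjusted p = 0.43 with an estimated correlation). Hml, which encodes the blood cell clotting protein hemolectin, rose from 376 and 221 counts to 4765 and 3698, a log2 fold change of 3.71 ± 0.42 (edgeR adjusted p = 0.0055). The target of Tg, the transglutaminase gene whose product crosslinks clot proteins, rose from 21938 and 44544 to 861000 and 786388, a log2 fold change of 4.60 ± 0.31 (edgeR adjusted p = 0.0022). In the BDGP6.54 annotation Tg lies on chromosome 2L from 8011405 to 8026898 on the plus strand. Its target also holds a copia element of 5146 bases (8013669 to 8018814) and a Doc element of 4720 bases (8018860 to 8023579), both in the intron between the exonic stretches that end at 8013103 and start at 8024517. Transposable elements make up 50.6% of this target. Of 22 targets with at least 500 bases of copia, Tg among them, 13 were higher and 3 lower. CG10887 had a log2 fold change of 3.95 ± 0.30 and CG44623 of 4.09 ± 0.25 (both chosen after their values were seen), so the files do not show how many of the Tg counts came from Tg exons. The clot gene fon had 3 and 4 counts in control and 63 and 88 in tumor (log2 fold change 4.33 ± 0.64, edgeR adjusted p = 0.0097), but its locus sum differed by 0.17 (adjusted p = 0.70) and its call ended without control 1, control 2 or tumor 2 (adjusted p up to 0.075). Idgf2, a chitinase-like growth factor gene, rose by 3.84 ± 0.20 and the transferrin gene Tsf1 by 1.65 ± 0.09, with locus sums at 2.97 and 0.69. Glt, for glutactin, rose from 10 and 20 to 1254 and 1144 counts, and its locus sum rose by 1.51. Idgf1 was listed at 0 in control and at 7126 and 7717 in tumor, with a locus sum that rose by 4.08. The list stayed past the threshold without targets rich in transposable elements (adjusted p = 0.015), a set that leaves out Tg, and lost it on the TPM scale (adjusted p = 0.083 to 0.11).

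**Figure D2:**
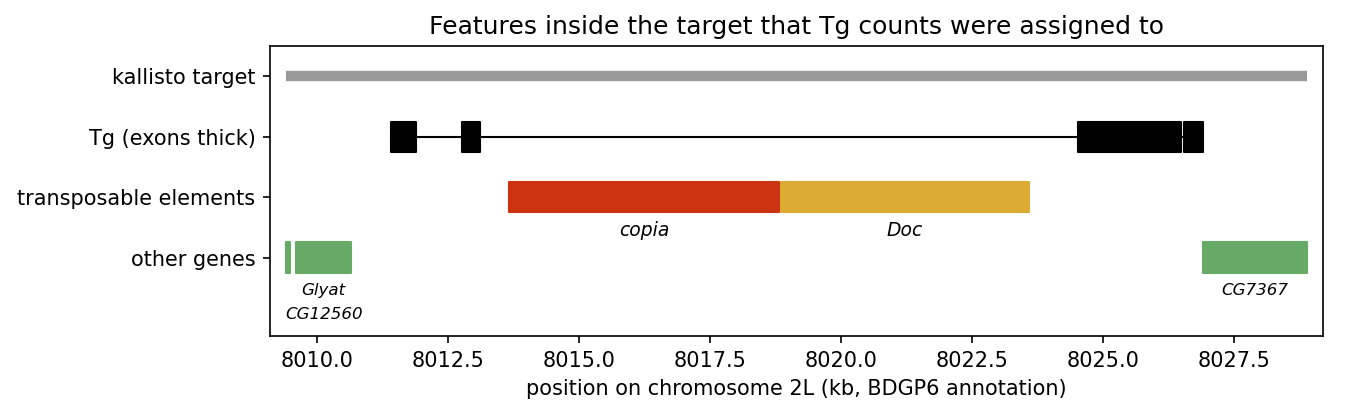
Map of the 19.5 kb kallisto target of Tg on chromosome 2L (horizontal axis, position in kb), drawn to scale, with the exons of Tg, annotated transposable elements and the parts of other genes that lie inside it. The copia element of 5146 bases and the Doc element of 4720 bases lie in an intron of Tg.

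Blood cell genes rose along with them. Of 20 tested members 9 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.017, adjusted p = 0.48 with an estimated correlation), and 4 of the 20 are also on the clotting list. NimC4, a phagocytic receptor gene, rose from 63 and 89 counts to 2089 and 2014, and NimC1, another such receptor gene, from 10 and 9 to 657 and 627. The JAK-STAT reporter gene vir-1 rose from 303 and 391 to 68966 and 39910, a log2 fold change of 7.22 ± 0.33. Col4a1, a type IV collagen gene that follicle cells also express, fell by 1.77 ± 0.10. The crystal cell genes PPO1, with 34 and 0 counts against 268 and 455, and PPO2, with 46 and 0 against 387 and 878, did not pass the threshold (edgeR adjusted p = 0.13 and 0.12; chosen after their values were seen). The receptor gene eater, also chosen afterwards, had 13 and 16 counts against 138 and 111, and its call ended without control 1, control 2 or tumor 1 (adjusted p up to 0.082). The list's call ended without control 2 (adjusted p = 0.052) or tumor 1 (adjusted p = 0.066) and on the TPM scale (adjusted p = 0.058 to 0.091).

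Secreted factors changed in both directions. Among 30 tested growth factors and cytokines 10 rose and 6 fell (12 and 6 adjusted over the list alone), and the list passed on locus sums (adjusted p = 0.026) but not on single genes (camera adjusted p = 0.08, adjusted p = 0.55 with an estimated correlation). The insulin-binding antagonist gene ImpL2 rose from 5333 and 4150 counts to 37443 and 59836, a log2 fold change of 3.27 ± 0.38 (edgeR adjusted p = 0.0059). The fibroblast growth factor gene bnl rose by 4.77 ± 0.27 and the Toll ligand gene spz by 2.98 ± 0.18. Pvf2, for a PDGF- and VEGF-related factor, rose from 6 and 17 to 2260 and 1568 counts, while the log2 fold changes of its relative Pvf1 (0.52 ± 0.27, edgeR adjusted p = 0.19) and of their receptor gene Pvr (-0.44 ± 0.19, edgeR adjusted p = 0.14) did not pass. Pvr was at 0.19 under scaling to ribosomal protein genes. The 3 unpaired ligand genes of the JAK-STAT pathway moved apart. The gene upd1, a marker of polar cells, fell by 5.29 ± 0.56, upd2 rose from 6 and 11 to 298 and 284 counts (5.03 ± 0.49), and upd3 rose by 1.44 ± 0.27. The upd3 call ended without control 1, control 2 or tumor 2 (adjusted p up to 0.091). The insulin-like genes Ilp6 and Ilp8 fell by 2.72 ± 0.12 and by 1.86 ± 0.17, with locus sums at -1.34 and -0.87. In the JAK-STAT list 6 of 15 members rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.62, adjusted p = 0.89 with an estimated correlation), with a median log2 fold change of 0.21 and a mean of -0.15. There, zfh1 rose by 2.44 ± 0.17, apt fell by 1.31 ± 0.11, and the feedback gene Socs36E had a log2 fold change of 0.61 ± 0.13 whose call ended without control 1 or either tumor library (adjusted p up to 0.09).

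JNK and Ras pathway targets rose. Some JNK targets, puc among them, are also on the list of immediate early and dissociation stress genes given below. Of 17 JNK targets 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 2.2e-05, adjusted p = 0.43 with an estimated correlation). The member that fell was Ilp8, with a log2 fold change of -1.86 ± 0.17. The matrix metalloproteinase gene Mmp1 rose from 208 and 239 counts to 14689 and 14085, a log2 fold change of 5.94 ± 0.09 (edgeR adjusted p = 4.8e-04), and its locus sum rose by 3.08. The feedback phosphatase gene puc rose by 1.84 ± 0.19 (locus sum 0.50), scaf by 5.71 ± 0.20, the ETS factor gene Ets21C by 3.88 ± 0.25 and Pax, for paxillin, by 1.88 ± 0.09. Mmp2, which is not on the JNK list, had a log2 fold change of 1.73 ± 0.49 (edgeR adjusted p = 0.049). The Mmp2 call ended without control 1 or either tumor library. Of 16 Ras-EGFR feedback genes and targets 10 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 1.2e-04, adjusted p = 0.43 with an estimated correlation). They included edl (2.89 ± 0.09), the ETS factor gene pnt (2.54 ± 0.08) and the EGFR inhibitor gene aos, which rose from 655 and 960 to 13262 and 18012 counts. The protease gene rho was listed at 0 in control and at 1532 and 1213 in tumor, with a locus sum that differed by -0.03. Among 21 apoptosis and DNA damage genes 10 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.027, adjusted p = 0.43 with an estimated correlation). The pro-apoptotic genes rpr and skl rose by 4.77 ± 0.37 and 5.89 ± 0.21 and the caspase inhibitor gene Diap1 by 1.39 ± 0.08. Dronc, an initiator caspase gene, was listed at 0 in control and at 899 and 967 in tumor, and its locus sum fell by 0.25. The apoptosis call ended without control 2 (adjusted p = 0.065), tumor 1 (adjusted p = 0.051) or tumor 2 (adjusted p = 0.054), with limma-voom (adjusted p = 0.053), on the TPM scale (adjusted p = 0.05 to 0.052) and on locus sums (adjusted p = 0.24).

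Junction genes rose in tumor. In the list of follicle polarity and junction genes 16 of 27 rose and none fell (16 and 0 adjusted over the list alone; camera adjusted p = 7.5e-05, adjusted p = 0.43 with an estimated correlation). aPKC itself is on this list. Among 16 septate junction genes 13 rose and none fell (13 and 0 adjusted over the list alone; camera adjusted p = 4.6e-05, adjusted p = 0.43 with an estimated correlation). Many septate junction genes, Gli, sinu and Mcr among them, are on both lists, so the lists do not count as separate results. Fas3, an adhesion gene that marks immature follicle cells, rose from 7504 and 10472 counts to 25037 and 24733 (1.41 ± 0.11). Gli rose by 3.10 ± 0.21 (locus sum 0.76), the claudin gene sinu by 2.41 ± 0.22, nrv2 by 1.36 ± 0.13 and Mcr by 1.00 ± 0.10. The locus sum of Mcr differed by 0.15 (adjusted p = 0.12). Of 15 epithelial-mesenchymal and invasion genes 7 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.037, adjusted p = 0.43 with an estimated correlation), among them cher, for filamin (1.62 ± 0.11). That call ended without control 1 (adjusted p = 0.12) or control 2 (adjusted p = 0.13), with limma-voom (adjusted p = 0.095), on ranks (adjusted p = 0.098) and on the TPM scale (adjusted p = 0.25 to 0.27). Of 19 tetraspanins, which are membrane proteins with 4 spans, 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.0039, adjusted p = 0.43 with an estimated correlation), with Tsp42El at 18 and 10 counts in control and 2649 and 1215 in tumor, Tsp42Ed (3.54 ± 0.28, locus sum 1.63), Tsp96F (1.89 ± 0.19) and Tsp42Ef (1.52 ± 0.16). The tetraspanin list lost its call on locus sums when members that share a sum were counted once (adjusted p = 0.14). Among 23 basement membrane and matrix genes 11 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.14, adjusted p = 0.71 with an estimated correlation). The type IV collagen gene vkg fell by 1.76 ± 0.11, close to its partner Col4a1, and the glypican gene dlp rose by 2.12 ± 0.13.

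Germline, yolk and eggshell genes fell. Control held many counts of yolk genes, although its tissue was described as restricted to follicles before yolk uptake. The libraries do not show whether the falls came from germline content, follicle stage or a change within follicle cells. Of 39 germline genes 26 fell and 1 rose (27 and 2 adjusted over the list alone; camera adjusted p = 1.0e-08, adjusted p = 0.43 with an estimated correlation). The RNA helicase gene vas fell from 4342 and 3348 counts to 182 and 592 (3.38 ± 0.70 lower on the log2 scale), although that call ended without control 1 or control 2 (adjusted p up to 0.09). The vas locus sum had a log2 fold change of -0.85, and on the same stretch lies vig, which was listed at 0 in control and at 10872 and 8039 in tumor, so the size of the vas fall is not settled. The differentiation gene bam fell from 1575 and 1189 to 64 and 57, with a locus sum at -0.62. The translational repressor gene bru1, ovo and qin had log2 fold changes of -4.52 ± 0.21, -3.26 ± 0.18 and -5.59 ± 0.24, against locus sums at -2.43, -1.10 and -0.68. The yolk receptor gene yl fell from 25512 and 29578 to 37 and 57, with a locus sum at -3.25. Of 9 meiosis genes 5 fell and none rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.0077, adjusted p = 0.43 with an estimated correlation), but the list lost its call on locus sums (adjusted p = 0.52). There, solo, which shares the stretch of vas and vig, fell by 2.81 ± 0.18, with a locus sum at -0.86. The gene mtrm had 1295 and 1454 counts in control and was listed at 0 in tumor while its locus sum rose by 0.81, and ord had 66 and 131 counts against 1 and 0, a call that ended without control 2 (adjusted p = 0.061). The log2 fold change of c(2)M was -1.10 ± 0.20, and its call ended without control 1 or control 2. It also ended with the replicate block (edgeR adjusted p = 0.052) and under scaling to ribosomal protein genes, at -0.45 (edgeR adjusted p = 0.19). Of 20 vitellogenesis and eggshell genes 11 fell and none rose (11 and 0 adjusted over the list alone; camera adjusted p = 3.9e-06, adjusted p = 0.44 with an estimated correlation). The yolk protein genes fell in both tumor libraries, Yp1 from 33487 and 41661 counts to 173 and 446, Yp2 from 52687 and 57310 to 1184 and 1624, and Yp3 by 2.45 ± 0.20. The locus sums of Yp1 and Yp2 were at -3.10 and -2.94. Inside the span of Yp1 lies asRNA:CR45601, which was listed at 0 in control and at 10894 and 8189 in tumor. Its locus sum was also at -3.10, so the size of the Yp1 fall is not settled. The eggshell patterning protease gene ndl fell by 7.91 ± 0.23 (locus sum at -3.05), and the chorion gene Cp19 went from 2375 and 3635 counts to being listed at 0, with a locus sum that fell by 3.73. Other chorion genes, chosen after their values were seen, differed widely between control 1 and control 2, with 38349 and 0 counts for Cp36, 116951 and 1544 for Cp38, 1748 and 43 for Cp7Fa, and 287 and 3431 for Cp15. Cp36 and Cp7Fa did not pass (edgeR adjusted p = 0.11 and 0.066), and the calls of Cp38 and Cp15 ended without tumor 1 or tumor 2. They also ended with limma-voom (adjusted p = 0.46 and 0.071) and with limma-trend on log2(TPM + 5) (adjusted p = 0.095 and 0.076). The locus sums in control 1 and control 2 were 169705 and 6285 for Cp38 and 3051 and 7066 for Cp15, so the inequality of Cp38 is not removed by adding the targets of its locus.

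Genes of follicle cell identity moved in both directions, with 10 of 21 higher and 6 lower (10 and 6 adjusted over the list alone; camera adjusted p = 0.50, adjusted p = 0.79 with an estimated correlation). The zinc-finger gene peb, also called hindsight, which Notch induces at the end of follicle cell division, fell from 13224 and 19896 counts to 320 and 264 (5.88 ± 0.17 lower on the log2 scale). Of 12 Notch targets 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.40, adjusted p = 0.71 with an estimated correlation), with a median log2 fold change of -0.36 and a mean of 0.17. The ligand gene Delta fell by 2.37 ± 0.18, E(spl)m4-BFM fell by 1.49 ± 0.16, and the glycosyltransferase gene fng rose by 1.74 ± 0.12. Among 36 cell cycle and DNA replication genes 3 rose and 11 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.26, adjusted p = 0.79 with an estimated correlation). The endocycle regulator gene fzr fell by 1.96 ± 0.11 and the mitotic cyclin gene CycB by 1.53 ± 0.14, with locus sums at -1.03 and -0.71. PCNA rose by 0.88 ± 0.08 while its locus sum fell by 0.49. The log2 fold change of Dp was -0.65 ± 0.08, it was 0.00 under scaling to ribosomal protein genes, and its call ended without control 1 (adjusted p = 0.051).

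Stress and glycolysis genes rose, and genes for ribosomes and the respiratory chain fell under the scaling used. Of 17 heat shock and chaperone genes 9 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0037, adjusted p = 0.43 with an estimated correlation). The co-chaperone gene stv rose by 2.60 ± 0.13 and the small heat shock gene CG14207 by 2.85 ± 0.11. In the small heat shock cluster Hsp22 was listed at 0 in control and at 29798 and 40370 in tumor, and its neighbour Hsp26 had 723 and 463 counts against a listing at 0 while its locus sum rose by 4.63. Of 13 ER stress and integrated stress response genes 10 rose and none fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.0043, adjusted p = 0.48 with an estimated correlation), among them Xbp1 (1.69 ± 0.08), Sil1 (1.91 ± 0.18), Irbp18 (1.72 ± 0.18) and CG10383, whose call ended without control 1 or control 2 (adjusted p up to 0.059). The ER stress list missed the threshold on locus sums (camera adjusted p = 0.088), where Irbp18 rose by 0.72. Of 15 glycolysis genes 11 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 2.9e-04, adjusted p = 0.43 with an estimated correlation). Pgi rose by 2.35 ± 0.09, the aldolase gene Ald1 from 7056 and 8250 counts to 34254 and 37867 (2.17 ± 0.12), and Gapdh2 by 2.08 ± 0.12. Their locus sums rose by 1.24, 2.17 and 0.96. Pglym78 was listed at 0 in control and at 5167 and 4195 in tumor, with a locus sum that rose by 0.31.

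Among 55 ribosomal protein genes 33 fell and 4 rose (37 and 4 adjusted over the list alone; camera adjusted p = 3.9e-06, adjusted p = 0.47 with an estimated correlation), whereas under scaling to these genes themselves, which sets their middle near 0 by construction, 7 fell and 8 rose and the list stayed lower than other genes (camera adjusted p = 0.007). RpS24 fell by 2.42 ± 0.09 (locus sum at -0.57) and RpL34a by 1.18 ± 0.08. RpL35 rose by 1.00 ± 0.08 while its locus sum fell by 0.48, and RpL24-like had 1077 and 1770 counts against a listing at 0. Of 50 nuclear-encoded respiratory chain genes 19 fell and 3 rose (19 and 3 adjusted over the list alone; camera adjusted p = 0.0062, adjusted p = 0.48 with an estimated correlation), and the ribosomal protein scaling gave 2 lower and 17 higher (camera adjusted p = 0.36). UQCR-6.4L fell by 5.69 ± 0.23, ATPsynbeta had a log2 fold change of -0.79 ± 0.09 and ND-PDSW of -0.89 ± 0.11, the last 2 of which did not pass under that scaling, and ND-13B rose by 2.52 ± 0.18 while its locus sum fell by 0.38. Of 50 mitochondrial ribosomal protein genes 19 fell and 1 rose (18 and 1 adjusted over the list alone; camera adjusted p = 0.0037, adjusted p = 0.43 with an estimated correlation, adjusted p = 0.068 on locus sums), against 9 lower and 14 higher under the ribosomal protein scaling, where the list kept its call (camera adjusted p = 0.0019). Here mRpL19 fell by 1.17 ± 0.11, mRpL45 rose by 0.99 ± 0.08, and mRpL38 had 1813 and 1902 counts against a listing at 0. That scaling moved the median of all genes by 0.65 on the log2 scale, to 0.67, and the medians of the 3 families were then 0.00, 0.32 and 0.12.

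**Figure D3:**
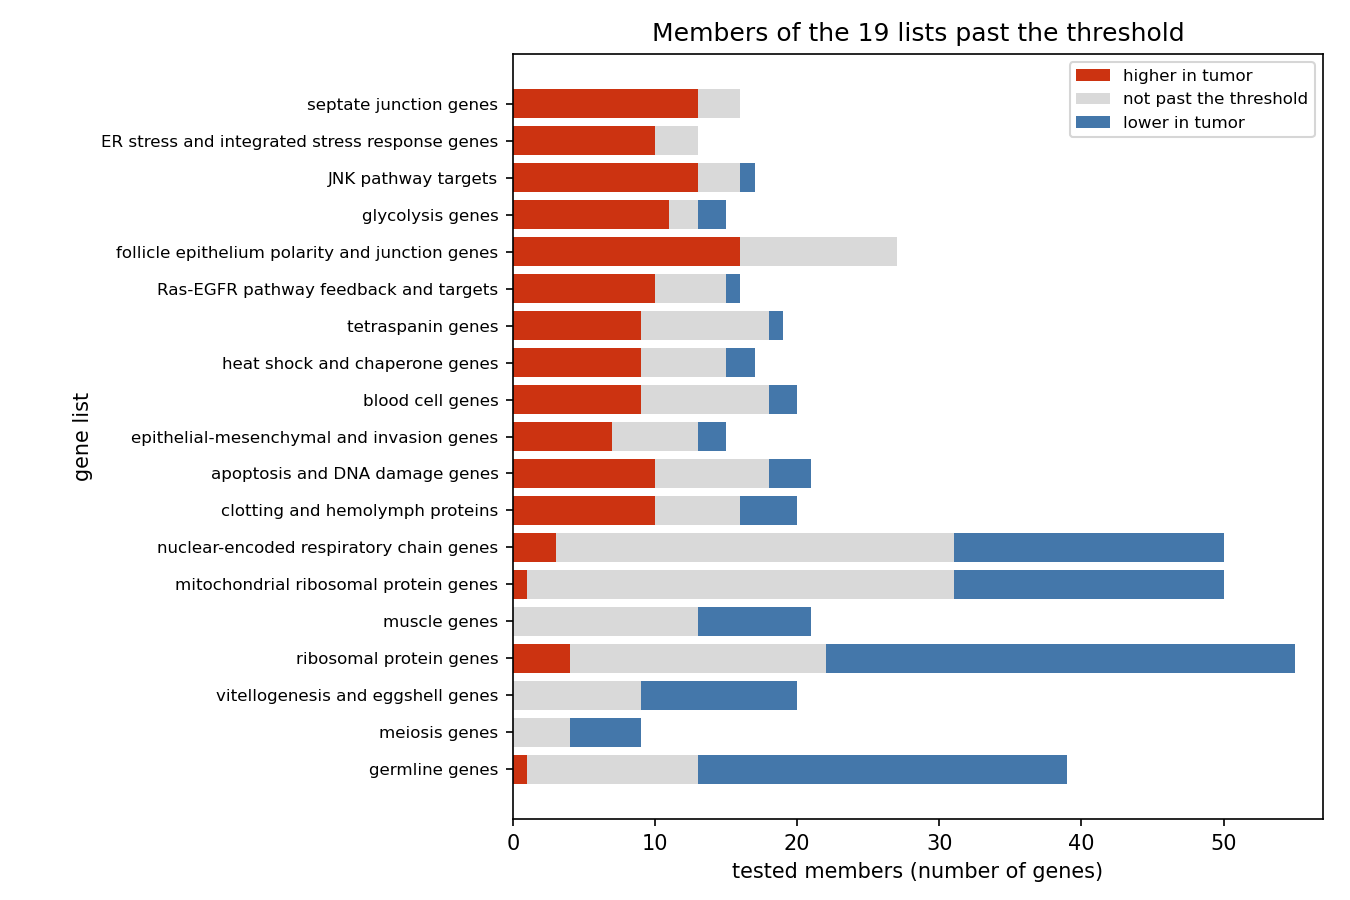
Tested members (horizontal axis, number of genes) of the 19 gene lists past the threshold of the camera test, with members higher in tumor in red, members not past the threshold in grey and members lower in tumor in blue. The germline list has 26 of 39 members lower, and the septate junction list has 13 of 16 higher.

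Markers of other tissues did not move together. Of 21 muscle genes 8 fell and none rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.71 with an estimated correlation), and control 2 held more of their counts than control 1. The giant muscle protein gene bt had 3329 and 7740 counts in control and 842 and 749 in tumor, Obsc had 460 and 1167 against 77 and 100, and TpnC73F had 571 and 1191 against 72 and 21, with a locus sum at -0.94. The call of TpnC73F ended without control 2 (adjusted p = 0.064) and that of Obsc without tumor 1 (adjusted p = 0.05). Mef2 had a log2 fold change of -0.85 ± 0.15 with a locus sum at 0.09, and its call ended without control 1 or control 2. It also ended on the TPM scale (limma-trend adjusted p = 0.064 to 0.14) and under scaling to ribosomal protein genes, at -0.20 (edgeR adjusted p = 0.43). The muscle list lost its call without control 2 (adjusted p = 0.052) or tumor 2 (adjusted p = 0.065), on locus sums (adjusted p = 0.10), with DESeq2 (adjusted p = 0.068) and with the fry test (adjusted p = 0.16). Lists for fat body (6 of 12 higher, 2 lower), neurons (3 of 10 higher, 2 lower) and trachea and gut (3 of 8 higher, 2 lower) did not pass (camera adjusted p = 0.21, 0.62 and 0.48; adjusted p = 0.48, 0.79 and 0.71 with an estimated correlation). Adjusted over the list alone, the counts were 6 and 2, 4 and 2, and 4 and 2.

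The genes with the largest fitted changes among well-counted genes were all near 0 in 1 group. Hsp22, CG42335, mt:tRNA:Gly-TCC, asRNA:CR45601, vig, Cpr64Ab, lncRNA:CR45336, Idgf1, CG11029, parvin, CG4194 and Pglym78 were listed at 0 in both control libraries. CG8545, mRpL9, Vm34Ca, osk, mt:ND5, snoRNA:Me18S-A425, eIF6, CG30338, CG18336, CG42806, CG4806 and Ak3 were listed at 0 in both tumor libraries. In each set of 12 the locus sum changed in the same direction past the threshold for 9, but often by little. Among the higher genes other than lncRNA:CR45336 these log2 fold changes ran from 0.26 for parvin and 0.31 for Pglym78 to 5.58 for CG42335. The locus sum of lncRNA:CR45336 had the same log2 fold change as its own count, so it is no check there. Among the lower genes they ran from -0.48 for snoRNA:Me18S-A425 to -2.69 for CG30338. Since 24 of 92 ribosomal protein genes were also listed at 0 in all 4 libraries, a listing at 0 is not read as absence here. No fold of the gene's own counts is given for the genes of both sets. In a ranking chosen after the data were seen, limited to genes whose exons lie mostly outside other targets, 214 of 670 tested genes were higher and 116 lower with the adjustment over all tested genes. At an average log2 CPM of at least 4, its top 6 higher genes were lncRNA:CR45336, beat-Vb, lncRNA:CR45736, smal, spok and scaf. Transposable elements make up 35.6%, 22.6% and 63.8% of the targets of the first 3. The discoidin-domain gene smal rose from 21 and 27 counts to 2681 and 5853, and spok, a paralog in ecdysone synthesis, from 21 and 40 to 858 and 2730, a call that ended without control 1 or control 2 (adjusted p up to 0.059). With the same limit, the top 6 lower genes were lncRNA:CR41601, klu, Marf1, CG12581, Ncc69 and laza. The zinc-finger gene klu fell from 3067 and 3607 counts to 88 and 62 (5.55 ± 0.21 lower on the log2 scale), and the meiosis regulator gene Marf1, 53.8% of whose target is transposable element sequence, fell by 4.08 ± 0.17.

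None of the remaining lists passed the camera test on the counts of single genes. Yorkie targets had 4 of 17 higher and 7 lower (adjusted p = 0.50), immune response genes 6 of 16 higher and 2 lower (adjusted p = 0.14), and serpins and clip proteases 6 of 22 higher and 3 lower (adjusted p = 0.37). Immediate early and dissociation stress genes (immediate early genes below) had 6 of 9 higher and 2 lower (adjusted p = 0.14), with a median log2 fold change of 1.31 and a mean of -0.66, and passed as higher on locus sums (adjusted p = 0.02). Oxidative stress genes had 9 of 21 higher and 3 lower (adjusted p = 0.089), lipid metabolism genes 6 of 18 higher and none lower (adjusted p = 0.29), proteasome subunits 6 of 23 higher and none lower (adjusted p = 0.87), and mitochondrial genome transcripts 1 of 5 higher and 1 lower (adjusted p = 0.62). With an estimated correlation the adjusted p was 0.71 for Yorkie targets, 0.57 for immune genes, 0.60 for serpins, 0.48 for immediate early genes, 0.46 for oxidative stress, 0.71 for lipid metabolism, 0.95 for proteasome subunits and 0.74 for the mitochondrial genome. Adjusted over the list alone, higher and lower counts were 4 and 7 for Yorkie targets, 7 and 2 for immune genes, 6 and 3 for serpins, 6 and 2 for immediate early genes, 10 and 3 for oxidative stress, 5 and 0 for lipid metabolism, 4 and 0 for proteasome subunits and 1 and 1 for the mitochondrial genome.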

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

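Locus sums, also with list members that share a sum counted once, resolved genes and the exclusion of small RNAs or of transposable elements were chosen only after the results were seen. Of 164 called genes named here, 144 stayed past the threshold in the same direction in each of the 17 alternatives set before the data were examined, and 20 lost it in at least 1, of which 18 did so when a library was left out, which leaves a lone sample that is assumed to vary like the others. Of the 19 lists, 13 stayed past the threshold in all of them but the estimated correlation. Leaving out 1 library gave 1095 to 1495 genes higher, 760 to 1507 lower, 9 to 12 lists higher and 6 to 7 lower. TMM on ribosomal protein genes gave 4426 genes higher and 902 lower, with log2 fold changes of 0.19 for Pvr and 0.00 for Dp. Limma-trend on log2(TPM + 1) gave 66.3% of calls higher and a median gene shifted by 0.24, and upper-quartile factors shifted it by -0.11. A stricter threshold lowers counts by its construction. A log2 fold change of at least 1 left 1141 genes lower, glmTreat against 1 left 877 higher and 665 lower, and an adjusted p under 0.01 left 992 and 851. Camera with an estimated correlation called 0 lists higher and 0 lower, with 1 in each direction at an unadjusted p under 0.05, while fry called 22 higher and 6 lower. Adjusted over the 670 resolved genes alone, 220 were higher and 122 lower. Without control 1, which held all control counts of Cp36, its log2 fold change was 7.15, and it was -17.38 without tumor 1, whose 36 counts are the only ones in tumor; both values rest on the small count added to groups at 0.

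Locus sums, which add counts of neighbouring genes by construction, called 4 lists lower in place of 7. Lists for secreted factors (adjusted p = 0.026) and immediate early genes (0.02) passed as higher on them, which they did not on single genes. So did those for oxidative stress (0.0063) and glutathione S-transferases (2.3e-04), where neighbours share the same sum and count more than once. Counting members with a shared sum once left these 2 near the threshold (0.048 and 0.032), ended the tetraspanin call (0.14) and again gave 4 lists lower. They turned the sign of these log2 fold changes, to -0.13 for Pvf1, 0.03 for Pvr, -1.16 for mt:tRNA:Gly-TCC, -3.10 for asRNA:CR45601, -0.86 for vig, 0.42 for eIF6, 0.70 for CG42806, -0.03 for rho, 0.81 for mtrm, 0.16 for c(2)M, 0.09 for Mef2, 4.63 for Hsp26, -0.25 for Dronc, -0.49 for PCNA, -0.48 for RpL35, -0.38 for ND-13B, 2.67 for GstD2 and 0.97 for GstO2. The small change of lncRNA:roX2 also turned, to 0.46 under scaling to ribosomal protein genes and to 0.05 to 0.06 on the TPM scale. For the other alternatives the cause was not tested.

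No sign of pairing by replicate number was seen: across genes, control 1 minus control 2 correlated at -0.015 with tumor 1 minus tumor 2. Larger differences between single libraries could hide a shared batch, so pairing is not excluded. With the replicate block, 1533 genes were higher and 1305 lower. Of the named genes 3 lost the threshold, upd3 (edgeR adjusted p = 0.051), vas (0.052) and c(2)M (0.052). So did 1 list (epithelial-mesenchymal and invasion genes, camera adjusted p = 0.057).

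Depth limits genes with few counts most: fon had 3 and 4 counts in control, upd2 had 6 and 11, and NimC1 had 10 and 9.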

Other observations

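Of the tests below, those on whole-locus changes, on other element families, on other cell types and on blood cells were chosen only after the result was seen. The wording of the equal-transfer explanation was narrowed after its value was seen, with its limits unchanged. A further test, on element insertions carried by 1 fly line, could not separate the explanations and was dropped. Several gene groups outside the main lists held large changes although none passed as a list on the counts of single genes. Of 51 cytochrome P450 genes, 13 were higher in tumor and 14 lower (15 and 14 adjusted over the list alone; camera adjusted p = 0.88, adjusted p = 0.95 with an estimated correlation). Cyp6a20 rose from 32 and 82 counts to 8005 and 6576 and Cyp6a9 by a log2 fold change of 3.60 ± 0.29, while the ecdysone-inactivating gene Cyp18a1 fell by 1.28 ± 0.08 (edgeR adjusted p = 0.002). Of 21 glutathione S-transferase genes 9 were higher and 5 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.18, adjusted p = 0.71 with an estimated correlation), with a median of 0.55 and a mean of -0.05. GstD4 rose by 4.33 ± 0.08, GstE2 by 3.46 ± 0.27 and GstD1 by 2.37 ± 0.23, with locus sums at 2.67, 1.60 and 0.93. GstD2 fell from 1545 and 1455 counts to 394 and 333 although its locus sum, the same as that of GstD4, rose, and GstO2 went from 1450 and 978 counts to a listing at 0 while its locus sum rose by 0.97. Of 22 ecdysone response genes 6 were higher and 9 lower (8 and 10 adjusted over the list alone; camera adjusted p = 0.37, adjusted p = 0.65 with an estimated correlation), and sad, for an enzyme of ecdysone synthesis, fell from 1083 and 1222 counts to 40 and 41, with a locus sum at -1.53. Among 17 insulin and FOXO response genes 6 were higher and 5 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.87, adjusted p = 0.93 with an estimated correlation), with the activin-like ligand gene daw rising from 348 and 237 to 9134 and 14778 counts and srl falling by 1.18 ± 0.10.

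Cuticle genes had 7 of 19 higher and none lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.14), Osiris genes 3 of 6 higher and 2 lower (3 and 2; camera adjusted p = 0.48), patterning genes 5 of 18 higher and 1 lower (4 and 1; camera adjusted p = 0.35), and odorant, gustatory and ionotropic receptor genes 12 of 40 higher and 5 lower (12 and 5; camera adjusted p = 0.23). With an estimated correlation these 4 had adjusted p of 0.48, 0.77, 0.71 and 0.48. TwdlE had 3 and 2 counts in control and 112 and 99 in tumor, Cpr47Ee had 2 and 0 against 487 and 353, and Osi19 had 1 and 1 against 130 and 91. The Hedgehog receptor gene ptc rose by 1.45 ± 0.20. The FGF receptor gene btl rose from 72 and 117 counts to 4064 and 5722, beside its ligand gene bnl, and its locus sum rose by 2.47. The lipogenic genes FASN1, SREBP and AcCoAS rose by 1.02 ± 0.10, 1.14 ± 0.10 and 3.30 ± 0.22 (the last with a locus sum at 1.53), and the lipase gene Lip4 fell by 4.10 ± 0.46. Chosen after their values were seen, Ldh, for lactate dehydrogenase, rose from 35 and 10 counts to 7114 and 10190 (8.49 ± 0.67), the transporter gene MFS3 from 8 and 12 to 12569 and 18880 (10.55 ± 0.41), and Hsp27 from 28 and 432 to 78474 and 68674 (8.35 ± 1.36). Their locus sums were at 5.88, 9.33 and 2.49. Of 135 small nucleolar RNA genes 75 were lower and 8 higher, but their targets are mostly flanking sequence, so this need not be a change of these RNAs. The dosage compensation RNA lncRNA:roX1, also chosen afterwards, had 2161 and 2474 counts in control and 374 and 289 in tumor, while its partner lncRNA:roX2 had 722 and 908 against 779 and 722 and did not pass (edgeR adjusted p = 0.43).

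Of the called genes, 669 had fewer than 3 counts in both libraries of 1 group, 359 of them higher in tumor and 310 lower. Whether counts were transferred equally to neighbouring targets stays open: the sharing targets changed the other way by 0.5 to 2 times the gene's own change in 8.52% of 587 such genes, against 8.08% on average over 1000 shuffles. In 60.3% of them the sharing targets changed by more than 2 times as much as the gene, so a transfer could be masked in most of them. A division of reads that is not settled between overlapping targets is a candidate explanation, because such calls made up 6.23% of 4432 genes with no exon sequence of their own and 0.874% of 1601 genes with 50% or more, a ratio of 7.12. The locus sum changed past the threshold in the same direction for 351 of the 669 and in the opposite direction for 141. The opposite sums argue against switching of the whole locus for those 141 genes. They do not argue against a change of the gene itself, since its neighbours can set the sign of the sum. The median size of the log2 fold change was 1.00 for the locus sums and 9.55 for the genes. In 31.1% of the 669 the locus sum changed the same way by 3 or more. There, whole-locus switching cannot be told apart from an unsettled division of reads for single genes, and a change in genotype stays open.

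Targets that hold copia or mdg1 retrotransposon sequence were often higher in tumor, Tg among them. All 40 targets with copia or mdg1 took 0.323% and 0.413% of the counts in control and 3.2% and 3.43% in tumor, of which the 4 copia targets with the most tumor counts, Tg, CG44623, CG10887 and beat-Vb, took 0.089% and 0.142% against 2.82% and 2.87%. Of 807 targets with other families 30.1% were higher, above the 22.5% of 7694 targets with none and below the 62.5% of the 40. An equal rise of all targets that hold transposable elements is argued against only in part, since copia and mdg1 were picked from these data. A smaller general rise stays open, and some other families rose about as often as copia (13 of 22 higher), such as Tirant (11 of 21) and Burdock (8 of 15). Reads of the element families themselves may account for the counts: leaving out beat-Vb, CG10887, CG42335 and lncRNA:CR45336, which drew attention to the pattern, 58.3% of 36 targets with at least 500 bases of copia or mdg1 were higher and 4 were lower, Tg and CG44623 being among the 36. CG43954 and Lasp, also among them, have identical counts. A copia copy did not always go with a rise. With 5144 to 5148 bases of copia, CG34347, CG3726, mbl, sls and bbg did not pass, and Nipped-A, for and toc were lower. Whether transcription of the elements or their copies in the background of the fly lines differ stays open, and the part of the Tg counts left without copia is not known.

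Blood cell genes were higher in tumor as a list, a call that several alternatives above ended. Of its 20 tested members 9 were higher and 2 lower, with a median of 3.36 on the log2 scale. Among the higher ones (chosen after their values were seen) were Sr-CI, with 51 and 37 counts against 721 and 856, and He, with 5 and 0 against 363 and 259. The call of He ended without tumor 1 or tumor 2. A smaller share of germline RNA would raise every other cell type alike, which is argued against as the only cause, since the medians were 1.77 for trachea and gut, 0.73 for fat body, 0.42 for neurons and -1.22 for muscle. The muscle list had a locus median of -0.28 and lost its call on locus sums, with the fry test (adjusted p = 0.16) and without control 2 or tumor 2, so a part of the rise from a changed share could remain. Blood cells carried with the tumor samples stay open, since the folds of the risen genes differed by more than their errors (Cochran's Q of 16.5 per degree of freedom), which cells added to different control levels could also give. Of the 20 genes tested, 12 were at 1 CPM or more in control tissue and 6 are on other lists, while 8 of the 9 that rose were under 10 CPM there, a share that the expression filter partly sets, so carried cells and expression in the tumor epithelium cannot be told apart.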
